A study of Homo sapiens with 4 samples.

How the data were processed

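Gene expression was measured in NGP cells, an established human neuroblastoma cell line, on 4 one-colour Agilent arrays, 1 per sample. Per the labels' protocols, total RNA was purified with DNase treatment on the column, and Cy3-labelled cRNA was made with a low-input kit. The labels assign 2 arrays to cells transduced with an HBP1 overexpression construct and 2 to untransduced parental cells. The series text calls the samples 2 biological replicates, and nothing in the labels says further that they came from separate cultures, so the p-values measure the spread between these arrays, which may be partly technical. All 4 arrays lay on 1 slide and were scanned together, per the file headers. The arrays labelled HBP1 filled row 1 of the slide and the parental arrays row 2, so row and group cannot be told apart, and a slide block could not be fitted.

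The deposited scanner files were written by Agilent Feature Extraction, version 10.5.1.1 per the file headers and version 9.1 per the submitters' processing notes. Their processed signal is an intensity per spot on a linear scale, background subtracted and spatially detrended by that software and not scaled between arrays, per the file headers. The deposited value table holds log2 values of the same arrays, and the method behind it is not given in the sources used here. Its columns had medians from 6.73 to 6.76 and followed, with r of at least 0.9999 across 42405 probes, a normexp background correction (offset 10) of the median signals with quantile normalization. The largest difference from that reconstruction was 0.128 on the log2 scale. The table was therefore read as log2, not centred per gene, with the parameters of the authors' steps unknown. It served only as an alternative. Its fold changes correlated with those of the scanner values at r = 0.917 across tested features, which are not independent replicates.

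Control spots and spots flagged as non-uniformity or population outliers were left out, and saturated spots were kept. From 285 to 335 non-control spots per array were flagged, and 0 were saturated. Log2 processed signals were averaged over the spots of a probe, and each array's 75th percentile over its non-control probes was subtracted. A probe was tested when it was well above background on both arrays of at least 1 group. Probes were named by their unversioned accession in an NCBI RefSeq gene table (assembly GRCh38.p14), used for names and gene order only. Of 42405 non-control probes, 25422 matched 1 symbol, giving 19483 symbols, and the other 16983 kept their probe identifier. A gene was represented by its detected probe with the highest mean signal. This left 25851 tested features, of which 15257 carried a symbol. Among 109 named genes, 17 had over 1 detected probe, and NCF1 was the only one whose probes differed in sign.

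Group differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as HBP1 minus parental on the log2 scale, with no covariate. The fit had 2 residual and 2.78 prior degrees of freedom per gene, and the number of arrays limits its precision. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested features, with a threshold of 0.05. Where a probe was well above background on 0 arrays of a group, the fold is a bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal well above background on that array. It is written as at least N-fold and leaves out the spread between arrays. It holds for the background-subtracted signal, not for a background method that adds an offset. Where the dimmer group's signals all lay above that lowest signal, the bound equals the fitted fold, and the fitted fold is given without at least.

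Before the data were examined, 30 gene lists, the test designs, the alternative settings and the rule for naming genes were fixed. The rule names HBP1, MYCN and ALK, the 14 genes with a symbol and the largest log2 change in each direction among those past the threshold whose groups did not overlap, and up to 4 members per list past the threshold with the largest change. Where no member passed, up to 2 with the smallest p are given as values. Not every gene selected by the rule is printed. Genes named outside the rule are marked as chosen after their values were seen. Lists with at least 5 tested members, 29 of the 30, were tested with camera in limma with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists. Each list's median was also placed among those of 10000 random lists of the same size matched on mean signal, which was chosen after seeing the data. The random lists could hold other members of the same list, and their genes were drawn independently. The percentiles are therefore descriptive and not p-values.

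The scripts were tested on simulated data with the real arrays' signals and spread. With 200 of 25851 features changed, limma recovered 0% of those changed 1.5-fold or 2-fold, 46% at 4-fold and 88% at 8-fold, and called 4 unchanged features. With 2000 changed, 4.2%, 47.2%, 92.2% and 97.4% were recovered at these folds, and 57 of 1262 calls were unchanged features. When the G1/S list was lowered by 0.25 on the log2 scale in simulated values, its camera adjusted p was 1.48e-09 with the preset correlation and 0.655 with an estimated one. The second test thus had little power at this size in a single simulated set whose genes varied independently. The real lists had estimated correlations up to 0.752, so the simulation does not show how either test behaves for correlated genes.

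The alternatives were other normalizations, probe filters, flagged spots kept, the deposited table, other variance priors, other probes per gene, a replicate block, and each array left out in turn. The planned normexp correction of mean signals was not run, because the files used here hold no such column, and normexp on median signals was added in its place. Scaling to the spike-in probes and cyclic loess between arrays were also added after seeing the data. Figures were drawn with matplotlib 3.10.9.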

Results

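The comparison set NGP cells labelled as transduced with an HBP1 overexpression construct against untransduced parental NGP cells, with 2 arrays per group. NGP is a neuroblastoma line with amplified MYCN. HBP1 is an HMG-box transcription factor known as a repressor of cell cycle genes, and the series title links it to ALK signalling and to MYCN activity. The question was which genes differ in cells given more HBP1. A control virus was not part of the comparison, so transduction and HBP1 were not separated.

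The arrays had signals well above background for 30985 and 31462 of 42405 probes in the cells labelled HBP1 (73.1% and 74.2%), and for 28184 and 30781 in parental cells (66.5% and 72.6%). Replicates correlated at r = 0.992 in cells labelled HBP1 and 0.993 in parental cells, across genes, and arrays of different groups at 0.975 to 0.980. The SD of the log2 difference between 2 arrays was 0.42 and 0.39 within the groups and 0.68 to 0.76 between them. No pair of arrays held identical values.

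The signal of the HBP1 probe was not higher in the cells labelled HBP1. Its log2 signal relative to the array's 75th percentile was -0.16 ± 0.07 (SD, n = 2) in the cells labelled HBP1 and -0.07 ± 0.09 (SD, n = 2) in parental cells. The difference was -0.09 (SE 0.14, adjusted p = 0.711 with limma), with a 95% interval from -0.46 to 0.28. The array had 1 named HBP1 probe, spotted at 2 places, well above background on all 4 arrays. Whether it lies inside the part of HBP1 carried by the construct is not given in the sources used here, so it does not check the labels, and the arrays are called labelled HBP1 throughout. MYCN, the amplified oncogene of this line, differed by -0.30 (SE 0.14, adjusted p = 0.221) and the receptor tyrosine kinase gene ALK by 0.23 (SE 0.14, adjusted p = 0.335) in the same limma fit, neither past the threshold. The sign for MYCN flipped under cyclic loess, to 0.01.

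Many genes differed in the cells labelled HBP1, and the largest changes were upward. TFPI2, encoding a secreted protease inhibitor, rose 118-fold, from a log2 signal of -4.10 ± 0.15 to 2.79 ± 0.07 (SD, n = 2 each; adjusted p = 0.00322 with limma). The neuropeptide gene NPY rose 52.7-fold, from 0.20 ± 0.06 to 5.92 ± 0.29, and the hormone gene SST at least 39.1-fold. PLPP4 rose 42.3-fold, with 0 of 2 parental arrays well above background. ADGRG2 rose at least 29.1-fold by its brighter probe (its other detected probe gave a log2 change of 2.74). STATH, a salivary protein gene, rose at least 30.1-fold, and the cadherin gene CDH13 at least 23.0-fold. Of the genes seen in both groups, GPRC5C rose 39.6-fold and the chemokine gene CXCL14 33.8-fold. KCNT1 rose 38.4-fold, with 1 of 2 parental arrays well above background. Other genes among the 14 largest increases were CMKLR1 (at least 18.5-fold), TDO2, an enzyme of tryptophan breakdown (at least 17.4-fold), and TGFBI (at least 14.9-fold). These bounds hold for the background-subtracted signal only. With normexp on median signals and an offset of 50, which shrinks folds of dim genes, the log2 changes were 2.00 for ADGRG2, 1.99 for STATH, 2.41 for SST, 1.76 for CDH13, 2.55 for PLPP4, 1.38 for CMKLR1, 1.36 for TDO2 and 1.33 for TGFBI, all past the threshold. KCNT1 and CXCL14 stood at 2.84 and 3.17 there, and TFPI2 and NPY at 5.71 and 5.50.

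Decreases were smaller. GRXCR2 fell 12.7-fold, with 0 of 2 arrays labelled HBP1 well above background. The myosin gene MYO1G fell 10.0-fold, from -2.19 ± 0.03 to -5.52 ± 0.05 (SD, n = 2 each; adjusted p = 0.0032 with limma). The neural transcription factor gene POU3F2 was 6.49-fold lower, from 0.71 ± 0.01 to -1.98 ± 0.02. ZFPM2 was 6.11-fold lower, and the axon guidance receptor gene DCC 5.73-fold lower, with 1 of 2 arrays labelled HBP1 well above background. GALNT17 was 4.43-fold, CA5B 4.35-fold, MAOA, an enzyme of monoamine breakdown, 4.28-fold, DSCR8 4.20-fold, and TMEM255A 4.16-fold lower, and MNX1 fell from 0.36 ± 0.14 to -1.64 ± 0.27. BMP3 fell 4.41-fold and PRSS30P 4.19-fold, each with 0 of 2 arrays labelled HBP1 well above background. SIX4 was 3.90-fold lower, with 1 of 2 arrays labelled HBP1 well above background. With normexp on median signals GRXCR2 stood at -1.35, MYO1G at -1.74, DCC at -0.75, DSCR8 at -0.96 and SIX4 at -0.65, all still past the threshold. BMP3 and PRSS30P stood at -0.49 each and did not pass.

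**Figure D1:**
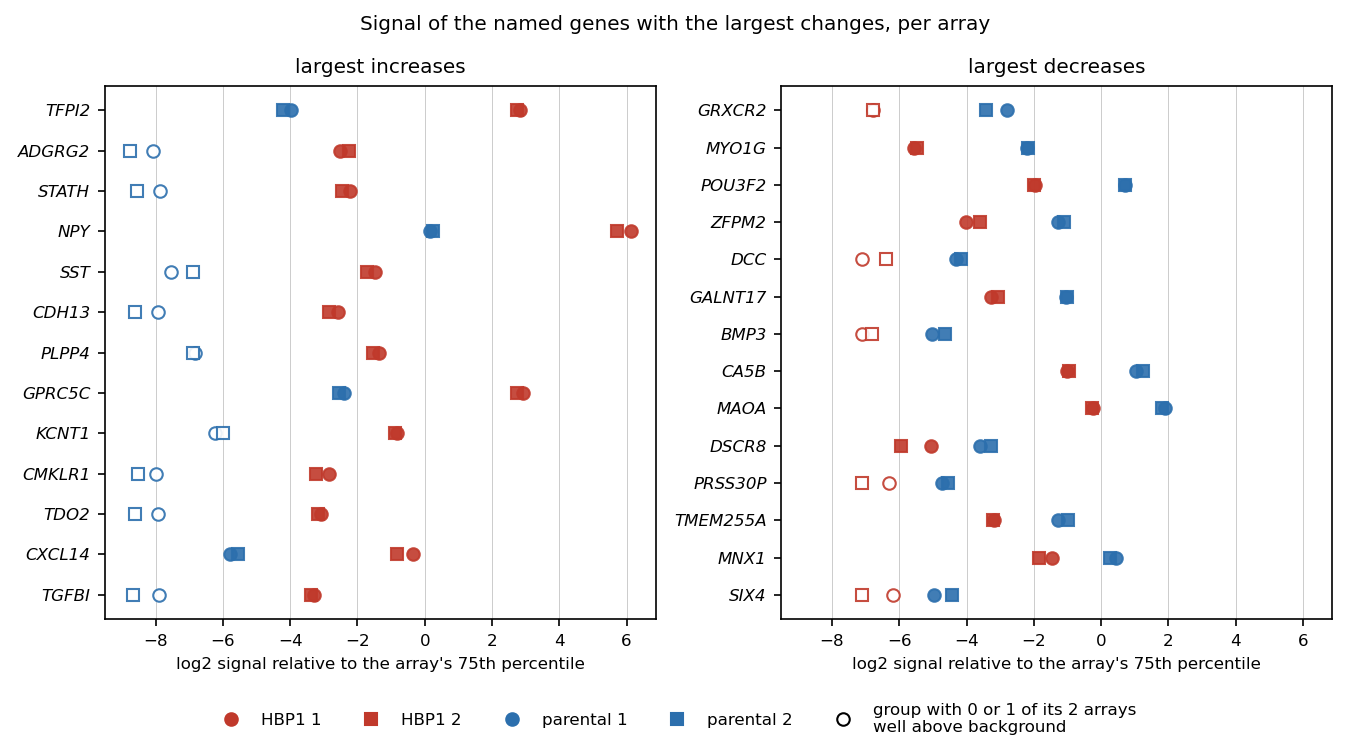
Log2 signal per array relative to the array's 75th percentile (horizontal axis) for named genes with the largest increases and decreases, 1 point per array, with open points for a group in which 0 or 1 of the 2 arrays was well above background. The arrays of the groups do not overlap for any of these genes, because the rule that chose them required it. TFPI2 moves from -4.10 to 2.79.

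In all, 2107 of 25851 features passed adjusted p 0.05 in limma, 1588 higher and 519 lower in cells labelled HBP1, so 75.4% of the calls were higher. Of those with a symbol, 1137 were higher and 355 lower. By unadjusted p the split was nearly even, with 3920 higher and 3784 lower, and it turned to 3272 higher and 5321 lower with median centring. Among the brightest of 10 equal-sized bins of features, 47 were called higher and 49 lower, and in the next 55 and 53. The counts at 4-fold or more were 423 higher and 25 lower, and at 16-fold or more 46 and 0. Groups were apart on all arrays for 62.4% of features, against 33.3% by chance with 2 arrays per group. Features not well above background on any array of a group were tested only through the other group: 333 of 670 missing in parental cells were called higher, and 16 of 32 missing in cells labelled HBP1 were called lower. Calls depended on each array. Without HBP1 replicate 1, 788 were higher and 393 lower, of which 710 and 153 were also called with all arrays. The counts were 525 and 62 without HBP1 replicate 2 (498 and 58 shared), 361 and 43 without parental replicate 1 (341 and 19 shared), and 389 and 32 without parental replicate 2 (356 and 10 shared). The split moved to 64.6% higher with median centring and to 55.8% with normexp on median signals. All 14 largest increases stayed past the threshold in every alternative that tested them (up to 18), against 7 of the 14 largest decreases. Without parental replicate 2 the calls for ZFPM2, DCC, BMP3, DSCR8, PRSS30P, MNX1 and SIX4 were lost.

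Genes of signalling feedback and rapid response were more often called higher than lower. Of 21 genes of MAPK feedback and ALK output, 10 were higher and 0 lower (14 and 1 adjusted over the list alone), with a median log2 change of 0.76. They included the transcription factor genes EGR2 (3.75, 1 of 2 parental arrays well above background) and EGR3 (at least 5.68-fold), the feedback inhibitor gene SPRY1 (2.11) and IER3 (2.09). Of 21 immediate early genes, 8 were higher and 0 lower (10 and 1 adjusted over the list alone), among them KLF2, at least 6.17-fold. EGR1, EGR2, EGR3 and IER3 were members of both lists, and EGR3 also of the mesenchymal list. Further lists shared members, among them RET (MAPK and noradrenergic), DKK1 (WNT targets and MYCN repressed) and ERBB3 (FOXO and Schwann). The lists are therefore not independent. With normexp on median signals EGR2 stood at 1.85, EGR3 at 0.61 and KLF2 at 0.68, all still past the threshold. The camera adjusted p was 1.88e-07 for the MAPK list and 1.78e-05 for the immediate early genes, and the adjusted p = 0.283 and 0.339 with an estimated correlation.

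Among WNT beta-catenin targets 10 of 20 were higher, 1 lower and 9 not past the threshold (11 and 1 adjusted over the list alone), with a median of 0.90. NKD2 rose by 2.36, MSX2 by 2.14, the transcription factor gene LEF1 by 2.10 and the stem cell receptor gene LGR5 by 1.99, on the log2 scale. MSX2 stood at 1.31 with normexp on median signals. TWIST1, named after its value was seen, was the member that fell (-1.18). For the list camera gave adjusted p = 3.29e-05, and the adjusted p = 0.283 with an estimated correlation. Of 11 genes reported as repressed by MYCN, 4 were higher and 0 lower (7 and 1 adjusted over the list alone): the tetraspanin gene CD9 (1.95), the integrin gene ITGA1 (1.70), the WNT antagonist gene DKK1 (1.45) and the neurotrophin receptor gene NGFR (0.72). Of 18 alternatives, NGFR lost its call in 11, DKK1 in 5 and ITGA1 in 3. The list's camera adjusted p was 0.000144, and the adjusted p = 0.283 with an estimated correlation.

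Neuroblastoma cell identity genes moved in both directions. Of 31 noradrenergic identity genes, 7 were higher and 2 lower (9 and 7 adjusted over the list alone). The imprinted gene DLK1 rose by 2.74, the vesicular monoamine transporter genes SLC18A2 and SLC18A1 by 2.17 each, and the receptor gene RET by 1.90, on the log2 scale. The transcription factor gene INSM1, named after its value was seen, fell (-1.08). The mean of the list was 0.26 and its median -0.04, opposite in sign, and camera gave adjusted p = 0.335. Fry gave adjusted p = 0.0542 for a shift on balance and 0.00103 for change in either direction. Of 29 mesenchymal identity genes, 9 were higher and 2 lower (13 and 3 adjusted over the list alone), with a median of 0.44. The homeobox gene PRRX1 rose 22.6-fold and ANXA1 at least 8.03-fold (log2 changes of 2.95 and 0.79 with normexp on median signals), while SIX4 and TWIST1 fell. Camera gave the mesenchymal list adjusted p = 0.00012, and the adjusted p = 0.339 with an estimated correlation.

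Of 43 neuronal differentiation genes, 6 were higher and 4 lower (12 and 8 adjusted over the list alone), and camera gave adjusted p = 0.115. Fry, which does not compare a list with other genes, gave adjusted p = 0.00835. The neuropeptide gene VIP rose 25.7-fold (log2 change of 2.98 with normexp on median signals). The members that fell were the neurofilament gene NEFL (-1.13), and, named after their values were seen, SNAP25 (-1.03), CNTNAP2 (-0.93) and SYN2 (-0.79), which encode synaptic or neuronal membrane proteins. The list passed the threshold in 6 alternatives, with adjusted p as low as 0.00647 with the authors' value table.

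Endothelial, fibroblast and Schwann markers were more often called higher than lower in cells labelled HBP1. Of 8 tested endothelial markers, 6 were higher and 0 lower (6 and 1 adjusted over the list alone), with a median log2 change of 2.22, among them the receptor genes KDR (3.08, 1 of 2 parental arrays well above background), ENG (3.02) and FLT1 (at least 2.48-fold) and VWF (2.30). Of 12 fibroblast and stromal markers, 8 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 1.61: POSTN rose at least 10.49-fold, the collagen gene COL5A1 by 2.47, DCN by 2.29 (3.78 by its other probe) and the smooth muscle actin gene ACTA2 by 1.96. Of 7 Schwann and glial markers, 5 were higher and 0 lower (6 and 0 adjusted over the list alone). CDH19 was at least 11.1-fold up, S100B 5.91-fold, with 0 of 2 parental arrays well above background, and PMP22 3.39-fold. Only 7 of the 13 fixed Schwann members passed the filter on dim probes, and without it the list shift went from 1.66 to 0.80 (camera adjusted p = 0.0052). The endothelial shift went from 1.76 to 1.49 without the filter (camera adjusted p = 1.26e-05) and was 0.68 at its lowest over the alternatives. When all 4 arrays had to be well above background, fewer than 5 members of either list were left, so neither could be tested. With normexp on median signals the log2 changes were 0.92 for POSTN, 1.01 for CDH19, 0.71 for S100B, 1.24 for ACTA2, 1.22 for KDR, 1.45 for ENG and 0.34 for FLT1, below the bounds or values above. FLT1 lost its call there and in 3 other alternatives, S100B lost it in 3, DCN in 4, and COL5A1 and ACTA2 in 2 each. Camera gave adjusted p of 3.29e-05, 2.67e-06 and 2.14e-05 for the endothelial, fibroblast and Schwann lists, and the adjusted p = 0.283, 0.339 and 0.283 with an estimated correlation. Of 11 immune markers, 2 were higher (2 adjusted over the list alone), LAPTM5 (at least 2.92-fold) and CD68 (1.35), and the list did not pass in camera (adjusted p = 0.185) but did in fry (adjusted p = 0.0461). With normexp on median signals LAPTM5 stood at 0.22 (adjusted p = 0.467) and CD68 at 0.86. The calls were lost in 4 and 3 alternatives.

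Stress and defence genes were higher in part. Of 35 p53 targets, 6 were higher and 1 lower (11 and 3 adjusted over the list alone), including the death receptor genes FAS (1.99) and TNFRSF10B (1.55), SERTAD1 (3.03-fold) and GDF15 (1.44). ABCA12, named after its value was seen, fell (-1.16). Of 35 interferon response genes, 7 were higher and 1 lower (10 and 1 adjusted over the list alone), with BST2 at least 4.03-fold, the HLA class I genes HLA-B and HLA-C by 1.80 and 1.64, and IRF1 by 1.40 (1 of 2 parental arrays well above background). UBE2L6, named after its value was seen, fell (-0.79). With normexp on median signals FAS stood at 0.92, BST2 at 0.44 (adjusted p = 0.179) and IRF1 at 0.26 (adjusted p = 0.344), and the calls of BST2 and IRF1 were lost in 5 and 6 alternatives. Camera gave adjusted p of 0.014 and 0.0018, and the adjusted p = 0.354 and 0.339 with an estimated correlation. Of 21 unfolded protein response genes, 4 were higher and 0 lower (13 and 0 adjusted over the list alone), DNAJC3 (1.12), EDEM1 (0.94), CRELD2 (0.86) and DNAJB11 (0.80). All 4 calls were lost without the filter on dim probes and whenever 1 array was left out. The camera adjusted p was 2.35e-06, and the adjusted p = 0.339 with an estimated correlation.

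The histone gene list shifted lower: 6 of 28 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.72. They included the replication-dependent histone H3 genes H3C7 (-1.40), H3C4 (-1.36) and H3C10 (-1.26, and -0.65 by its other probe). H3C10 lost its call in 6 of 18 alternatives, and H3C7 and H3C4 in 4 each. The camera adjusted p was 1.71e-07 with the preset correlation of 0.01. With an estimated correlation, which was 0.562 for this list, the camera adjusted p was 0.373. Of 30 hypoxia and glycolysis genes, 4 were lower and 1 higher (16 and 3 adjusted over the list alone), with a median of -0.55. ALDOC (-1.17) and PGK1 (-0.82), enzymes of glycolysis, and ANKRD37 (-0.87) fell, as did ENO2 (-0.80), named after its value was seen. P4HA2, a collagen prolyl hydroxylase gene, rose (1.70). Of 18 alternatives, PGK1 and ANKRD37 lost their calls in 10 each, ALDOC in 4 and P4HA2 in 2. Camera gave the hypoxia list adjusted p = 0.0133, and the adjusted p = 0.414 with an estimated correlation. The call was lost with quantile normalization (adjusted p = 0.0831) and cyclic loess (adjusted p = 0.0509).

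Cell cycle, MYC target and ribosomal protein lists shifted slightly downward with few single calls. Of 57 G1/S and DNA replication genes, 1 fell, GINS2, part of the replicative helicase (-0.80), with 0 adjusted over the list alone. The GINS2 call was lost in 9 of 18 alternatives. Of the 57 genes, 52 had negative values, and the list median was -0.27. Of 60 G2/M and mitosis genes, 0 passed (0 adjusted over the list alone) and the median was -0.27, with the survivin gene BIRC5 at -0.58 and PTTG1 at -0.60. Camera gave adjusted p of 3.34e-05 and 7.72e-05, and the adjusted p = 0.283 and 0.339 with an estimated correlation. The G2/M call was also lost in the authors' value table, where the shift was -0.13 (adjusted p = 0.103).

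Of 70 MYC family targets, 0 passed (0 adjusted over the list alone), and the median was -0.24, with DCTPP1 at -0.61 and BOP1, of ribosome biogenesis, at -0.56. The camera adjusted p was 0.00178, and the adjusted p = 0.339 with an estimated correlation. The call was also lost with quantile normalization (shift -0.10), the authors' value table (-0.05) and cyclic loess (-0.12). All 67 cytosolic ribosomal protein genes had negative values, with a median of -0.33, and 0 passed (0 adjusted over the list alone). RPL29 stood at -0.61 and RPS15A at -0.53. The list's camera adjusted p was 4.1e-07, and the adjusted p = 0.536 with an estimated correlation. That call was lost with the authors' value table (-0.10, adjusted p = 0.194) and cyclic loess (-0.10, adjusted p = 0.480). The 65 ribosome biogenesis genes had 0 calls (0 adjusted over the list alone), a median of -0.14 and a camera adjusted p of 0.0227, with IMP3 at -0.52, and the adjusted p = 0.373 with an estimated correlation. The list lost its call in 8 alternatives. Its median lay at percentile 75.5 among random lists matched on mean signal, whose own median was -0.17. The list was therefore not lower than equally bright genes. Polycomb complex genes had 1 of 27 lower (1 adjusted over the list alone), PHF1 (-0.96), and a camera adjusted p of 0.0351, with adjusted p = 0.354 with an estimated correlation. The list call was also lost in 8 alternatives, and the PHF1 call in 7.

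Of 7 genes earlier reported as repressed by HBP1, 0 passed (0 adjusted over the list alone) and the median was -0.12. Camera, which compares the list with other genes, gave adjusted p = 0.578, and fry, which does not, gave adjusted p = 0.0461. DNMT1, a DNA methyltransferase gene, stood at -0.48 and NCF1 at 0.39, and its other probes ranged from -0.11 to 1.06. Of 4 genes reported as activated by HBP1, 3 were tested, too few for a list test. FOXO targets (4 of 29 higher, 5 and 6 lower adjusted over the list alone; GADD45B at least 6.71-fold, or 0.73 with normexp on median signals, ERBB3 1.16, or 0.66 there and 2.18 by its other probe, BCL6 0.90 and IRS2 0.80), apoptosis regulators (2 of 28 higher, 4 and 4 lower adjusted over the list alone; BIK 1.69, or 0.51 and not past the threshold with normexp, and BMF 0.99, or 1.77 by its other probe) and HDAC complex genes (HDAC10 0.99 higher, or 0.65 with normexp, and RCOR2 -0.80 lower of 28, 1 and 0 adjusted over the list alone) did not pass as lists in camera, with adjusted p of 0.669, 0.675 and 0.134. Of 30 ATF4 stress response genes, 1 fell, PHGDH, an enzyme of serine synthesis (-0.79; 0 adjusted over the list alone; list adjusted p = 0.0655 in camera and 0.0315 in fry). Of 18 alternatives, RCOR2 lost its call in 11, PHGDH in 10, IRS2 in 9, BCL6 in 8, and ERBB3, BMF and HDAC10 in 5 each. Of 24 cholesterol biosynthesis genes 0 passed (0 adjusted over the list alone; list adjusted p = 0.467), with LSS at -0.80 and ACAT2 at -0.65. Of 5 genes often amplified in neuroblastoma 0 passed (0 adjusted over the list alone; list adjusted p = 0.450), with DDX1 at -0.37.

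**Figure D2:**
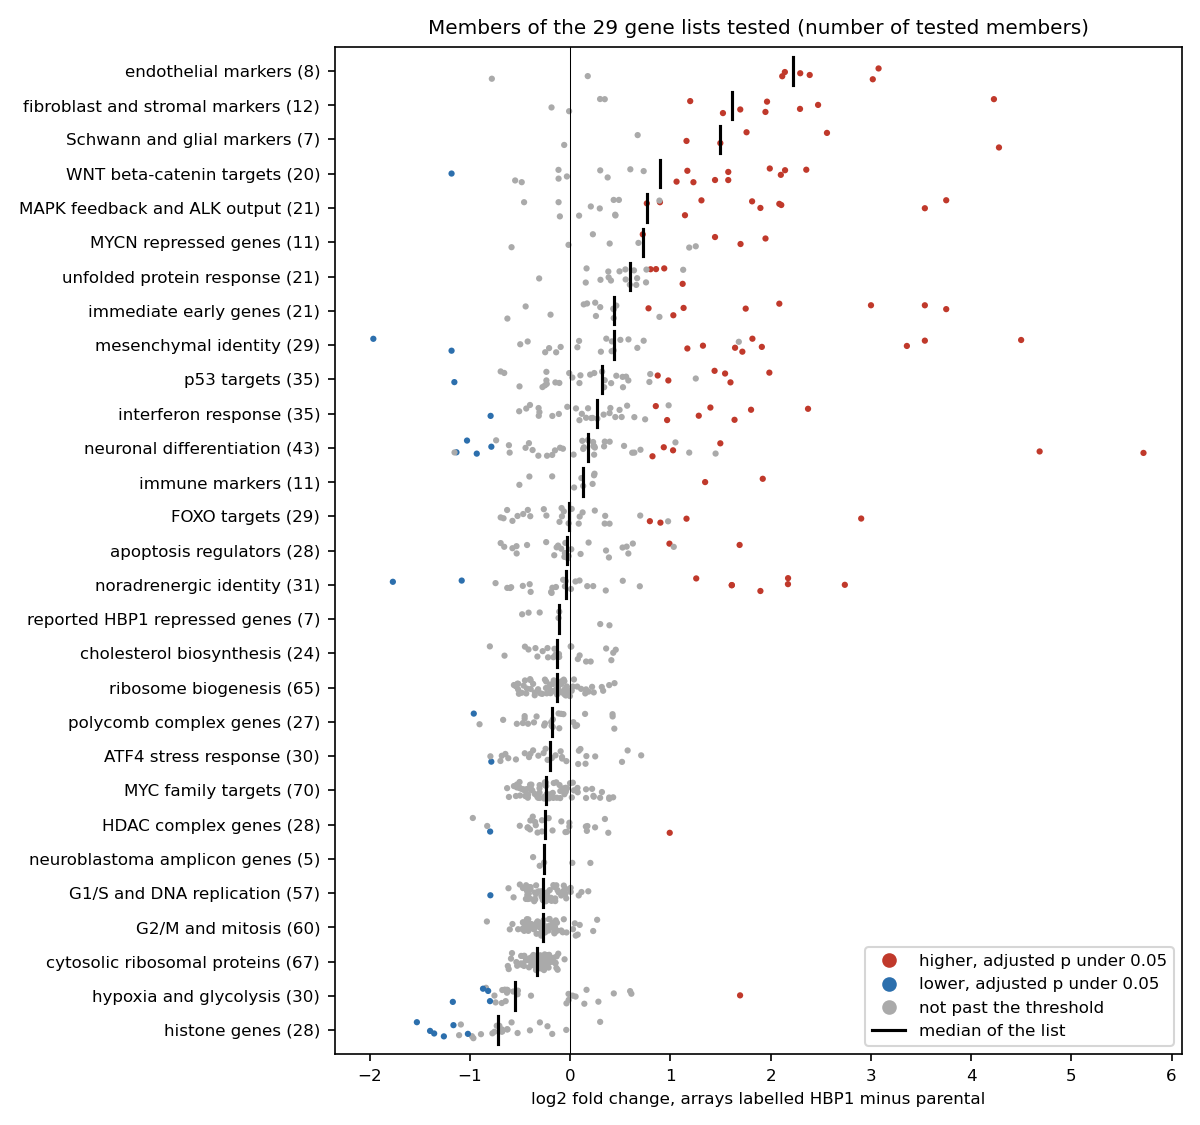
Log2 fold change of each tested member (points) of the 29 lists, arrays labelled HBP1 minus parental, with the median of each list as a bar and calls past adjusted p 0.05 in colour. Endothelial markers have the highest median, 2.22, and histone genes the lowest, -0.72.

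Across the 29 lists, 11 passed as higher and 8 as lower in camera with the preset correlation, and 0 with an estimated correlation. By fry 18 passed. The reported HBP1 repressed, neuronal, ATF4 and immune lists passed in fry and not in camera. The MYC target (adjusted p = 0.0507 in fry), ribosome biogenesis (0.0542), ribosomal protein (0.137), histone (0.0542) and hypoxia (0.0525) lists passed in camera and not in fry. Fold change fell slightly with signal: the median was 0.25 in the dimmest of equal-sized bins of features and -0.25 in the brightest, against -0.06 over all.

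**Figure D3:**
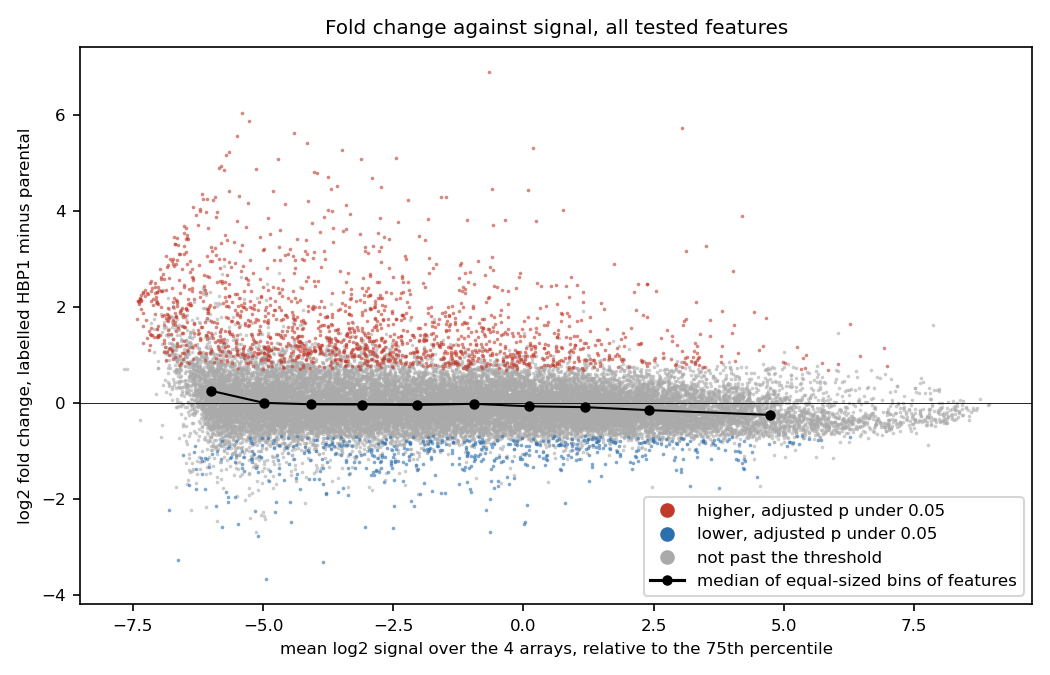
Log2 fold change of each tested feature (vertical axis) against its mean log2 signal over the 4 arrays, with calls past adjusted p 0.05 in colour and the median of equal-sized bins of features as a line. The line runs from 0.25 in the dimmest bin to -0.25 in the brightest.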

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

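The normexp, spike-in and cyclic loess settings were chosen after seeing the data. All 14 largest increases passed in every setting that tested them, of 18. The count of 2107 genes was 422 at adjusted p 0.01 (381 higher, 41 lower) and 4483 at 0.1 (2715 higher, 1768 lower). A 2-fold minimum left 272 lower. Without a filter on dim probes 351 passed (323 higher, 28 lower), over 36457 tested features. With an intensity trend in the prior 3814 passed, 1627 of them lower. Genes lower numbered 843 with the authors' value table, 1236 with normexp on median signals and 310 with spike-in scaling. Leaving out 1 array gave 404 to 1181 genes, 361 to 788 higher and 32 to 393 lower, and a lone array was assumed to vary like the other group. The deviations of same-numbered arrays correlated at 0.139, with only 2 pairs, so the numbers were not taken as pairing, and with the replicate block 1245 were higher and 279 lower. The HBP1 difference ranged from -0.17 to -0.02 and never passed. The MYC family target shift of -0.24 lost its call with an estimated correlation (adjusted p = 0.339), quantile normalization (-0.10, adjusted p = 0.303), the authors' value table (-0.0519, adjusted p = 0.680) and cyclic loess (-0.12, adjusted p = 0.263). The G1/S shift of -0.31 lost it only with an estimated correlation (adjusted p = 0.283). The G2/M shift of -0.30 lost it with an estimated correlation (adjusted p = 0.339) and in the authors' value table (-0.13, adjusted p = 0.103; range over its alternatives 1.05e-05 to 0.339). The noradrenergic list passed only in the authors' value table (0.36, adjusted p = 0.0382; range to 0.700). Among results not called, the sign turned for the amplicon list with quantile normalization (0.0126), the authors' value table (0.0750) and cyclic loess (0.0159), for cholesterol genes in the authors' value table (0.0209), for apoptosis regulators without parental replicate 2 (-0.00149, leave-one-out range up to 0.113), for NCF1 with the second probe (-0.11) and normexp (-0.00662), and for MYCN with cyclic loess (0.0141). The cause was not tested. Of the other list results under alternatives 395 kept their side of the threshold, 20 lost the call and 10 gained one. The named genes that lost their call numbered 46 without the filter and 22 to 49 when 1 array was left out. The slide block and normexp on mean signals were not run. Low signal over background limits folds for genes at the floor in parental cells.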

Other observations

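The brightness, HBP1 probe, fibroblast and neighbour tests, with their limits, were set after related values had been seen, and the neuropeptide and POU sets were assembled after the first members had been noticed.

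Some neuropeptide and hormone precursor genes beyond NPY, SST and VIP were higher. Of 33 tested precursors, 10 were higher, among them CRH, which encodes corticotropin-releasing hormone (3.88), CARTPT (4.12), PNOC (4.81, 1 of 2 parental arrays well above background), CCK (at least 6.51-fold), the granin gene CHGB (1.61) and VGF (1.15). NPPA fell by 1.17. Among all genes with a symbol, 1137 of 15257 were higher. With the 4 genes first noticed left out (NPY, SST, VIP and PNOC), 6 of 29 were higher (Fisher's exact test, two-sided, p = 0.0179). Those 6 include CHGB and VGF, which were already members of the noradrenergic and MAPK lists. The set was also assembled from the same arrays, so a wider rise of these genes is only a hypothesis. POU domain factor genes, which encode neural and other transcription factors, showed 4 of 11 lower: POU3F2 (-2.70), POU3F4 (-1.91), POU4F1 (-1.90) and POU4F2 (-1.66). Without the 3 first noticed, 1 of 8 was lower (Fisher's exact test, two-sided, p = 0.170), so a family-wide fall was not shown.

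HBP1 signal did not rise in the cells labelled HBP1. A saturated or dim probe was argued against, since 0 of its spots were flagged as saturated or at background. A probe outside the part carried by the construct stays open, because the array held only 1 named HBP1 probe and its place in the construct was not known. A mislabelled group, or low transgene RNA at harvest, was not tested.

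Stromal, Schwann and endothelial markers were higher in the cells labelled HBP1, by a median log2 change of 2.14 over the 19 called markers. For admixed fibroblasts, of 19 abundant fibroblast transcripts low in parental cells, 12 were higher. Of the rest, 4 (COL5A2, TAGLN, LGALS1 and LOX) had an upper 95% limit below 2-fold. Low meant below the 75th percentile, and LGALS1 lay near it at -0.37. The fold that admixture gives depends on each transcript's parental level and on its level in fibroblasts, which was not measured. A fixed 2-fold limit therefore cannot decide for or against admixed fibroblasts. For a copy number difference, 71 tested neighbours of these markers had a median of 0.17 (bootstrap 95% interval 0.03 to 0.23). This lay slightly above the median of -0.06 over all features and far below the 2.14 of the called markers. The values argue against a gain shared by these loci that is as large as the marker change. A pooled median cannot exclude a gain at some loci. Admixed fibroblasts, a copy number gain at some loci and an effect of HBP1 or of transduction itself stay open. The design cannot separate HBP1 from transduction.

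Ribosomal protein, MYC target and cell cycle lists were lower, as was the median of bright genes. After cyclic loess, which removes a trend with signal, the ribosomal protein shift went from -0.37 to -0.10 (SD of members 0.13 before and 0.15 after). Its call ended because the shift itself shrank. These genes had a mean log2 signal of 7.55, against 4.73 in the brightest of 10 bins, so loess may remove their own shift with the trend. Their median of -0.33 also lay below the -0.25 of brightness-matched lists, so trend and list cannot be told apart. The MYC target shift went from -0.24 to -0.12 (SD 0.27 and 0.25) and its call also ended, so trend and list cannot be told apart there, since about as much of the shift remained as was removed. The G1/S shift of -0.31 became -0.21 (adjusted p = 0.0104 with camera; up to 0.283 over its alternatives) and the G2/M shift of -0.30 became -0.20 (adjusted p = 0.0175; up to 0.339), which argues against the trend as their whole source. Among brightness-matched random lists the medians lay at percentiles 1.22, 14.5, 3.11 and 1.38 for the ribosomal protein, MYC target, G1/S and G2/M lists. These percentiles ignore correlation between list members, estimated at 0.752 for the ribosomal proteins. The random lists could also hold members of the list itself, so the percentiles do not decide. An effect of the group stays open as untested.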
